A study of Mus musculus with 2 samples.

How the data were processed

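RNA was taken from Vγ6 γδ T cells that had been stained with antibodies and sorted by flow cytometry from thymi of newborn mice, WT or MHC class II KO, with 1 array per genotype and 2 arrays in all. Whether a sample pooled several animals is not given in the sources used here. Per the labels, total RNA was extracted with TRIzol, purified on columns, amplified, and labelled with biotin for whole-transcript GeneChip arrays. RMA (robust multi-array average, which corrects background, brings arrays to one distribution and summarises probes) and Affymetrix Expression Console 1.4.1 were named per the submitters' processing notes. The variant of RMA and its settings are not given in the sources used here, nor is the genome build behind the rows, so no coordinates are printed.

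The deposited values are intensities on a linear scale, 1 per transcript cluster, for 65956 rows on each array. They ran from 6.45 to 480711 on the WT array and from 6.71 to 487523 on the MHC class II KO array, with medians of 40.1 and 38.2. A 16-bit scanner cannot read above 65535, and 767 and 742 rows lay above that. The values are therefore not plain scanner readings, and the step that took them past the ceiling, which the sources do not describe, could have widened or narrowed every fold given here. The number of arrays limits the precision, since no spread between replicates can be had.

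The log2 of each intensity was taken, and the measure was the log2 signal of the MHC class II KO array minus that of the WT array. Row names came from the platform's annotation, which can be old. Of the rows, 30604 had 1 gene symbol, 2146 several and 33206 none, and rows with several or none were left out of all gene counts. Symbols were updated through the gene identifier where the RefSeq gene table of assembly GRCm38.p6 allowed, which matched 22818 rows and changed 827 symbols. That table also gave the order of genes along chromosomes. Of several rows with the same symbol the brightest was used, leaving 30142 genes. For 170 genes with at least 2 different rows above background, the differences of 2 rows of a gene had a Pearson correlation of 0.767 across genes, and the SD of their gap was 0.27.

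The background of each array was the 95th percentile of 1228 olfactory receptor rows, which T cells are not known to use. It came to a signal of 61.3 on the WT array and 58.2 on the MHC class II KO array. A gene was kept when at least 1 array was above background, which left 14494 genes, 13710 of them above it on both. A gene above background on 1 array has only a bound, so its fold is given as at least the brighter signal over the background of the other array. No fold is given for a gene below background on both. Of the olfactory receptor rows, 78 passed this filter and 1 of those was 2-fold or more apart.

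With 1 array per group no test, standard error or p-value was possible. Genes were counted at a 2-fold threshold. For each of 32 gene lists fixed before the data were examined, the median difference of its members above background was placed among 10000 random lists of the same size, drawn from 20 bins of mean signal. A list was described as standing apart when this percentile was under 2.5 or over 97.5, and lists with fewer than 5 members above background got member values alone. The lists covered T cell biology, the cell cycle, metabolism, stress and the markers of other cells of the thymus.

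The rule for the genes named in the text was also fixed beforehand. It took the 12 highest and 12 lowest differences among genes above background, leaving out predicted models, small RNAs, sensory receptors and receptor gene segments. It added 31 genes chosen whatever their values and up to 4 members of each list with the largest absolute difference. This gave 149 genes, and 5 of the 31, among them Cd74, Cd27, Rag1 and Trdc, had no row with their symbol alone and were not analysed here.

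The alternatives were centring the differences on their median, quantile normalization, a loess correction of the difference on mean signal (fraction 0.3), raising values under background to it, averaging a gene's rows, 4 other background filters, thresholds of 1.5-fold and 3-fold, leaving out predicted models and small RNAs, unmatched random lists, means in place of medians, and lists without shared members. Counting rows with identical values once, and percentiles of the lists that stood apart under these alternatives, were added after the data were seen.

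The steps were tested on simulated data made from the 14494 genes of this comparison, with 200 genes given a known change. Of 100 genes changed by 1.5 on the log2 scale 99% were counted as 2-fold, and of 100 changed by 2 it was 100%, while 6 unchanged genes were counted. Of 100 unchanged lists of 20 genes 3 fell outside the middle 95%, and 100 of 100 lists shifted by 0.3 were over the upper limit. The simulated differences were independent normal draws with the robust SD of genes of like signal. The real differences had an SD of 0.35 against a robust SD of 0.25, and real genes vary together. These counts therefore check the steps and do not estimate how many genes or lists on the real arrays are false. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.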

Results

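Gene expression was measured in Vγ6 γδ T cells, a T cell subset that develops in the fetal and perinatal thymus and carries a γδ receptor built with the Vγ6 chain. The cells were sorted from the thymus of 0-day-old C57BL/6 mice that were wild type (WT) or lacked MHC class II (MHC class II KO), the surface molecules that present peptides to CD4 T cells. Each group was represented by 1 array, so no difference here has a replicate check, an error or a test, and the differences describe these 2 arrays. The WT array had 25902 of 65956 rows above its background, and the MHC class II KO array had 26004. The background, set from olfactory receptor genes, lay at a log2 signal of 5.94 on the WT array and 5.86 on the MHC class II KO array. All differences are the log2 signal of the MHC class II KO array minus that of the WT array.

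The comparison of the 2 arrays asked which genes are expressed differently by Vγ6 γδ T cells when MHC class II is missing, with the cells that make interleukin 17A as the study's focus. The genes for the interleukin 17 cytokines, Il17f and Il17a, were lower on the MHC class II KO array by log2 differences of -2.88 and -1.57. The gene for the inhibitory receptor CTLA-4, Ctla4, was lower by -3.46. Genes of mitosis were higher as a group, and so were markers of double positive and αβ thymocytes. Arg1, which encodes an enzyme that splits arginine, was higher by 3.03, and Ccr6, a chemokine receptor of IL-17-producing cells, by 1.46.

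Of 14494 genes above background on at least 1 array, 115 were at least 2-fold higher on the MHC class II KO array and 167 at least 2-fold lower, together 1.95% of those genes. With values under background raised to it, which uses bounds in place of measured values, 107 were higher and 117 lower. Counting rows with identical values once, an alternative chosen after the data were seen, gave 113 higher and 98 lower, so the excess of lower genes rests on such rows. Predicted gene models and small RNAs made up 40 of the higher and 123 of the lower genes. Without them the split turned, with 75 genes higher and 44 lower. The log2 signals of the 2 arrays had a Pearson correlation of 0.992 across genes above background, and genes are not independent replicates. The median difference of these genes was 0.04 and its robust SD was 0.25.

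**Figure D1:**
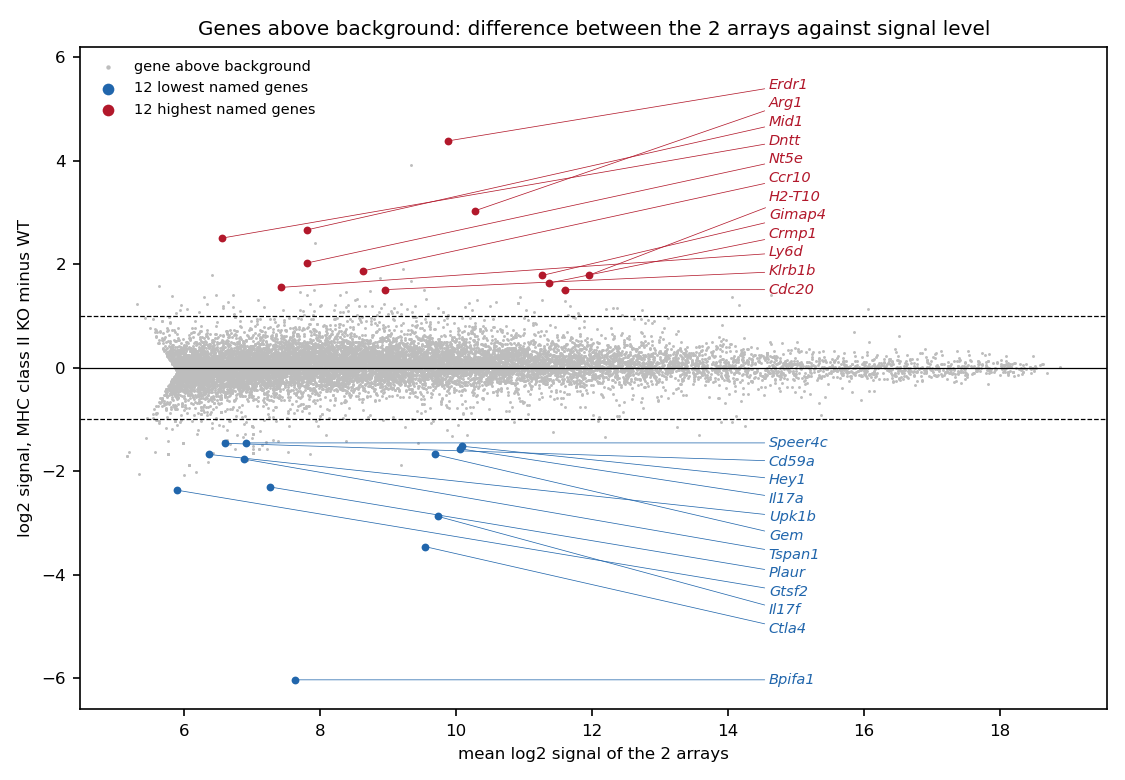
The difference between the 2 arrays (log2 signal, MHC class II KO minus WT, y axis) is plotted against the mean log2 signal of both (x axis), with 1 grey point per gene above background and dashed lines at 2-fold. The 12 highest named genes run from 1.51 (Cdc20) to 4.39 (Erdr1) and the 12 lowest from -1.45 (Speer4c) to -6.03 (Bpifa1, plotted at its measured value on the MHC class II KO array, which is below background).

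Among the 12 named genes with the lowest differences, Bpifa1, which encodes a secreted protein of the airway lining, stood first with a log2 signal of 10.66 on the WT array. It was not above background on the MHC class II KO array, so it was at least 27.7-fold lower there. Ctla4 went from a log2 signal of 11.28 to 7.82, and Plaur, the gene for the urokinase receptor, from 8.41 to 6.11. Gem, which encodes a small GTP-binding protein, differed by -1.68 and Hey1, a transcriptional repressor downstream of Notch, by -1.52. Tspan1 differed by -1.77, Cd59a by -1.46 and Speer4c by -1.45. Gtsf2 and Upk1b hold their places by measured values of -2.37 and -1.68, but they were above background on the WT array alone, which bounds them at 2.32-fold and 2.54-fold lower or more.

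Among the 12 named genes with the highest differences, Erdr1 differed by 4.39 and Mid1 by 2.67 (1.79 as the mean of its 2 rows). Dntt, which encodes the enzyme that adds untemplated nucleotides to rearranging receptor genes, was above background on the MHC class II KO array alone and at least 3.68-fold higher there. Nt5e, the gene for the surface enzyme CD73, differed by 2.02, and Ccr10, a chemokine receptor, by 1.87. The MHC class I-like gene H2-T10 differed by 1.79, Gimap4 by 1.78, Crmp1 by 1.64, Ly6d by 1.55 and Klrb1b by 1.51.

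The genes of MHC class II itself were lower on the MHC class II KO array. H2-Ab1, the β chain gene of the I-A molecule, had a log2 signal of 7.68 on the WT array and 6.67 on the MHC class II KO array, where it was still above background. H2-Eb1 went from 6.95 to 5.98, and H2-Aa from 6.09 to 5.08, which was not above background. The labels do not say which class II gene was disrupted, and the place of the probes relative to the deleted part is not known, so these values check the labels only in part. Of 12 measured genes of MHC class II and its processing machinery, 7 were above background. H2-Ab1, H2-Eb1 and H2-Oa were at least 1.5-fold lower, H2-Aa is bounded at only 1.17-fold lower, and Ctss, a lysosomal protease gene, was higher by 0.74. Their median difference was -0.60, at the 0.01 percentile of random lists matched on signal, but it went to -0.22 when values under background were raised to it, and with no background filter the list lay at percentile 10.8 and did not stand apart. The 12 genes of MHC class I and its processing machinery all had differences above 0, with a median of 0.26 (percentile 99.6). Psmb9, a subunit gene of the immunoproteasome, which makes peptides, and Tapbp, the gene for the loading factor tapasin, differed by 0.49 and 0.47, and none of the 12 reached 1.5-fold. Markers of double positive and αβ thymocytes were also higher on the MHC class II KO array (median 0.59, percentile 100). Whether a share of such cells would raise or lower the class I list was not tested.

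The IL-17 programme, a list of genes typical of γδ T cells that make interleukin 17, showed no common shift. Of 37 members above background, 5 were at least 1.5-fold higher, 3 at least 1.5-fold lower and 29 within 1.5-fold. The median was 0.03 (percentile 39.5) and fell below 0 when differences were centred on the median of all genes. The cytokine genes Il17f and Il17a were the lowest members, going from log2 signals of 11.18 to 8.30 and from 10.85 to 9.28. The title of the series points the other way, to more IL-17A-producing cells without MHC class II, although it speaks of cells and the arrays of transcripts. At the other end stood Ccr6 and the membrane protein gene Tmem176b (1.28). The third member at least 1.5-fold lower was Ahr, a ligand-activated transcription factor gene (-0.92), which is named here after its value was seen. The interleukin 23 receptor gene Il23r differed by -0.12 and the interleukin 1 receptor gene Il1r1 by -0.04. The transcription factor genes Maf, Sox13 and Zbtb16 differed by 0.03, 0.14 and 0.47, Maf changing sign with the scaling, and the kinase gene Blk by 0.47. On the same arrays the double positive and αβ thymocyte markers had a median of 0.59.

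The interferon gamma and cytotoxic programme also had no common shift. Of 17 members above background, 1 was at least 1.5-fold higher and 2 at least 1.5-fold lower when bounds are used. The median was 0.02 (percentile 43.7), below 0 under each of the other scalings and -0.33 without members shared with other lists. Nkg7 and the granzyme gene Gzmb were lower by -1.25 and -1.13, and Tbx21, the gene for the transcription factor T-bet, was higher by 1.17. Ifng was not above background on either array. The effector cytokine list had a median of -0.00 (12 members, percentile 30.3, above 0 after quantile normalization), with Il17f and Il17a at its low end and Csf2 (0.63) and Tnf (0.56) at its high end.

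**Figure D2:**
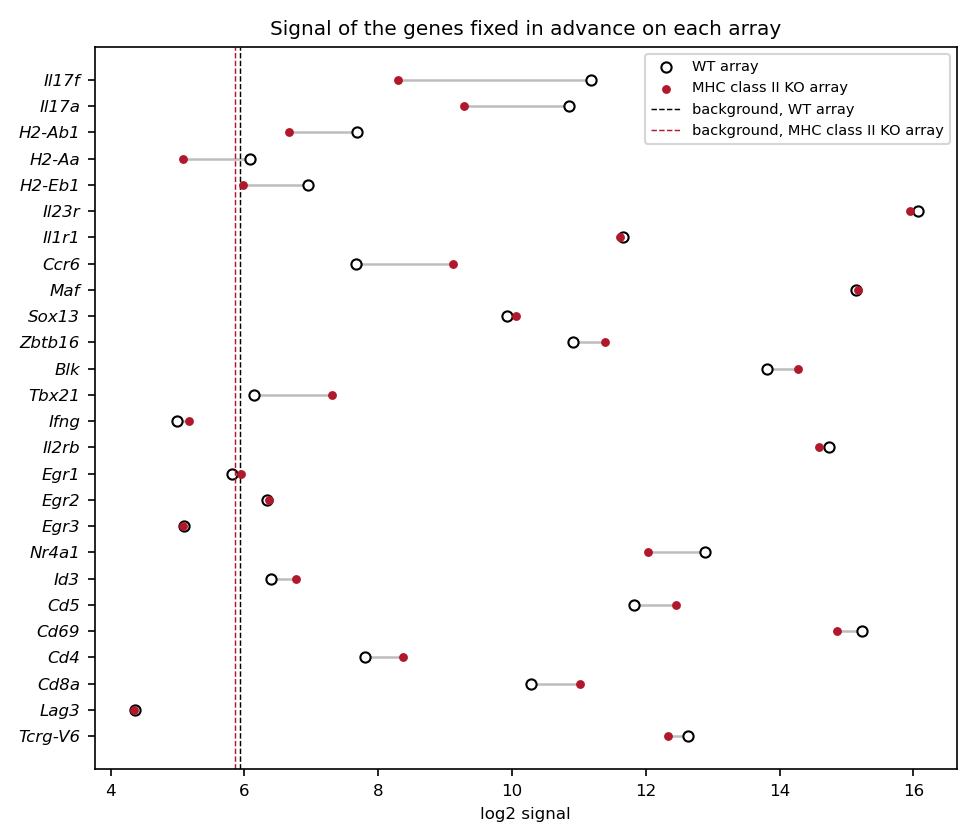
Log2 signal (x axis) of 26 genes fixed in advance, with an open circle for the WT array and a filled circle for the MHC class II KO array, and dashed lines at each array's background. Il17f and Il17a have the longest lines to the left, from 11.18 to 8.30 and from 10.85 to 9.28, while Il23r, Maf and Il2rb differ by less than 0.15.

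Genes that mark the strength of T cell receptor signalling went both ways. Of 26 above background, 4 were at least 1.5-fold lower and 3 at least 1.5-fold higher, and the median was -0.09 (percentile 0.86). After Ctla4, the lowest members were the nuclear receptor genes Nr4a2 (-1.32) and Nr4a1 (-0.86), which are switched on by receptor signalling. Dusp2, a phosphatase gene, was higher by 1.19 and Cd5, a negative regulator of the receptor, by 0.63. The activation marker Cd69 differed by -0.37, Id3 by 0.37 and Egr2 by 0.02 (its sign changing with the scaling). Egr1 was above background on the MHC class II KO array alone and by a small margin. Egr3 and Lag3 were not above background. The list no longer stood apart without Ctla4, at percentile 6.48, and without members shared with other lists its median was -0.0020 at percentile 24.6. The proximal signalling machinery had a median of 0.22 (20 genes, percentile 99.8), with the phosphatase gene Ptpn6 at 1.01 and Themis at 0.74. The double positive and αβ thymocyte markers, which include Themis, were higher on the same array as well (median 0.59), so a share of such cells is not separated from a change in the Vγ6 cells.

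The γδ receptor genes had a median of -0.08 (8 genes, percentile 8.20). The Vγ6 gene Tcrg-V6 was above background on both arrays, with log2 signals of 12.64 and 12.33, and Trgv7 was higher by 1.11 on the MHC class II KO array. The median of the early lymphoid transcription factors was 0.03 (25 genes, percentile 42.0, below 0 under 2 of the 3 other scalings), with Bcl11b at 0.66 and Lef1 at -0.51.

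Surface receptors held some of the larger single differences. Among 24 homing receptors and adhesion molecules, 4 were at least 1.5-fold higher and 2 at least 1.5-fold lower (median 0.15, percentile 93.6). Ccr10, Ccr6 and Ccr4 (1.33) were higher, and Cxcr4, a receptor that retains cells in tissue, was lower by -1.31. Among 28 cytokine receptors the median was 0.11 (percentile 91.6), with Il2ra, the high-affinity interleukin 2 receptor chain, at 1.19, Il17ra at 0.74, Tnfrsf1b at -0.76 and Il2rb at -0.14. Among 15 inhibitory and costimulatory receptors the median was 0.20 (percentile 97.48, just inside the range of random lists), with Slamf6 at 1.17, Cd226 at 1.11 and Cd96 at 0.90 opposite Ctla4.

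Mitotic genes were higher as a group. All 29 genes of G2/M and mitosis had differences above 0, and 18 were at least 1.5-fold higher (median 0.65, percentile 100). Cdc20, which activates the anaphase-promoting complex, differed by 1.51, the spindle checkpoint kinase gene Ttk by 1.18 and the spindle assembly gene Tpx2 by 1.02. The 28 genes of G1/S and DNA replication had a smaller median of 0.16 (percentile 96.7), with Ccne2 at 1.13 and Rrm2 at 0.93. The double positive and αβ thymocyte markers, some from cells that divide, were higher on the same array (median 0.59), so the share of such cells and division of the Vγ6 cells are not separated here.

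Among 24 genes of the type I interferon response the median was 0.24 (percentile 99.9), with 18 differences above 0 and 2 genes at least 1.5-fold higher, Igtp (0.69) and Stat2 (0.61). Rtp4 went the other way (-0.43). Igtp is named for its induction by interferon gamma, so this list does not separate type I interferon from interferon gamma. The thymocyte marker list was higher on the same array (median 0.59, percentile 100), and its part in the interferon list was not tested. NF-κB targets had a median of 0.07 (21 genes, percentile 70.6, below 0 after the loess correction), although the feedback inhibitors Tnfaip3 (-0.77) and Nfkbia (-0.59) were lower. Apoptosis regulators had a median of 0.00 (15 genes, percentile 28.3) that was below 0 under each of the other scalings, with Bcl2, which protects cells from death, at -0.61. Metabolic and housekeeping lists lay within the range of random lists. Their medians were -0.07 for glycolysis (19 genes, percentile 5.28), 0.02 for oxidative phosphorylation (32 genes, percentile 39.0, below 0 under 2 of the other scalings), 0.16 for cholesterol synthesis (17 genes, percentile 90.0) and -0.02 for ribosomal proteins (19 genes, percentile 16.4). The immediate early and dissociation stress genes had a median of 0.06 (20 genes, percentile 73.3), with Fosl2 at -1.11 and Hsph1 at 1.02.

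**Figure D3:**
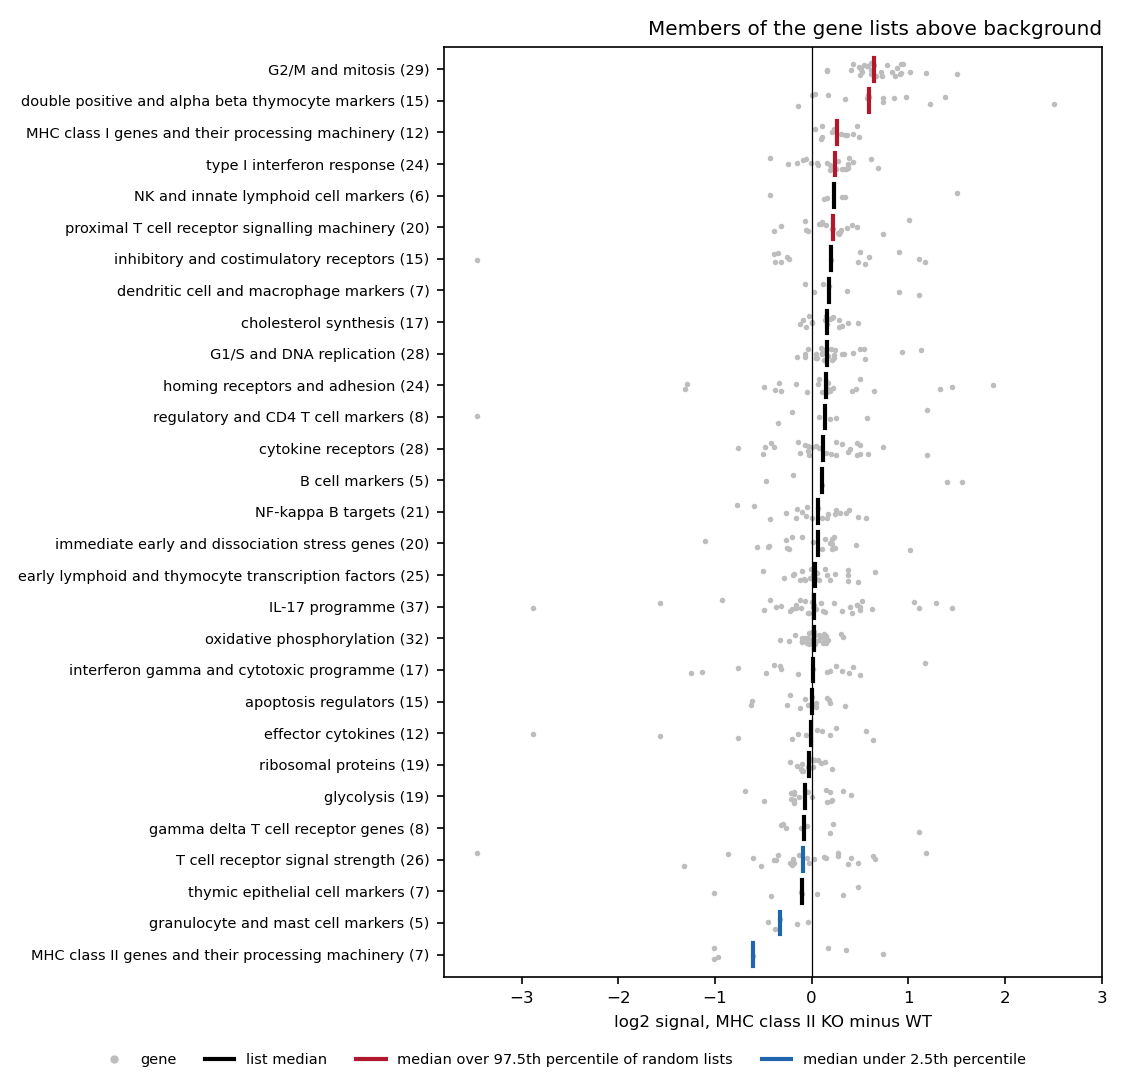
Each grey point is the log2 difference (x axis, MHC class II KO minus WT) of a gene above background, with 1 line per gene list (y axis, number of genes in brackets) and a bar at the list's median. Coloured bars mark the 8 of 29 lists outside the middle 95% of random lists, from -0.60 for MHC class II to 0.65 for mitosis.

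Markers of other cells that a thymus sort could hold were compared in the same way. Of 15 markers of double positive and αβ thymocytes above background, 8 were at least 1.5-fold higher when bounds are used and none lower (median 0.59, percentile 100). Besides Dntt, the CD8 β chain gene Cd8b1 differed by 1.38, Aqp11 by 1.23, Cd24a by 0.97, Cd8a by 0.74 and Cd4 by 0.57. Of the 15 markers, 13 had differences above 0 and 2 below. The share of such cells named beside the lists above is read from these markers alone. The V and J segments of the αβ receptor genes, a group chosen later, did not follow them (85 segments, median 0.03, percentile 54.5). The median was 0.13 for regulatory and CD4 T cell markers (8 of 11 genes, percentile 82.0) and 0.11 for B cell markers (5 of 16 genes, percentile 76.0). For NK and innate lymphoid cell markers it was 0.23 (6 of 12 genes, percentile 96.2). The B cell list held Ly6d and Ighm (1.41). Only 7 of 25 dendritic cell and macrophage markers were above background (median 0.18, percentile 91.5), with Irf8 at 1.11 and Cd68 at 0.91. Granulocyte and mast cell markers had a median of -0.33 (5 of 20 genes, percentile 2.26), led by S100a9 at -0.46, but with values under background raised to it the median was -0.17 at percentile 9.87 and the list did not stand apart. Thymic epithelial cell markers had a median of -0.10 (7 of 19 genes, percentile 30.2). Krt8 and Epcam, above background on the WT array alone, were at least 1.18-fold and 1.17-fold lower. Cd83 and Ly75, above background on the MHC class II KO array alone, were each at least 1.07-fold higher. Of 18 mesenchymal and endothelial markers 3 were above background (Sparc -0.14, Pdgfrb 0.05, Pecam1 0.11), and of 12 red blood cell and platelet markers 2 (Gp9 -0.36, Hbb-y -0.22). The X-inactivation RNA Xist was lower by -0.56 on the MHC class II KO array, and the Y-linked genes Eif2s3y, Uty and Kdm5d were higher by 0.58, 0.62 and 0.75, in the same comparison as every gene group above. Xist and these Y-linked genes were above background on both arrays, as a mix of female and male cells on each would give. The sources do not state the sex of the animals or any pooling.

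The sizes of all folds rest on a scale whose making is known only in part, since the deposited values pass the ceiling of a 16-bit scanner. The percentiles compare genes within these 2 arrays, where genes vary together, and are no p-values.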

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

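The tests of exchanged labels, of dilution, of the scaling of Il17a, of windows along the chromosomes and of the Y-linked genes were chosen after the results they bear on had been seen.

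Rows with no gene symbol entered no gene count or gene list, but did enter row counts and the scaling and filters set from all rows. Of 11044 such rows above background, 193 were at least 2-fold higher on the MHC class II KO array and 185 at least 2-fold lower. The highest of them differed by 3.90.

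The lower signal of the MHC class II genes on the MHC class II KO array may come from the knockout or from antigen-presenting cells carried through the sort. The dendritic cell and macrophage markers had a median of 0.18, opposite in sign to H2-Ab1 at -1.01. That was the outcome set in advance as going against carry-over, but only 7 of 25 markers were above background, so a small share of such cells would not show and carry-over stays open. Thymic epithelial cell markers, which that test left out, had a median of -0.10 (7 of 19 genes, percentile 30.2), and carry-over of those cells was not tested. Exchanged labels would put the MHC class II genes higher on the array labelled MHC class II KO, or level if the deleted part leaves their transcripts. H2-Ab1 was lower by -1.01 and H2-Eb1 by -0.97, which is -3.54 and -3.78 robust SD of genes of like signal. That SD is a spread across genes and not between replicates. An exchange alone would not account for these values, but an exchange together with unequal carry-over, which stays open, is not excluded.

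Il17a and Il17f were lower on the MHC class II KO array while the IL-17 programme as a whole was not. Dilution of the MHC class II KO sort by other cells would lower the other programme members by about as much, and the median of those 35 genes was 0.047. Scaling would have to bring Il17a near other genes of like signal, and under 3 other scalings the value nearest to 0 was still -6.76 robust SD of such genes. These scalings moved the median of all genes by at most 0.06 in size (-0.06, loess), too little to do so. They do not test the undescribed step that took values past the ceiling of the scanner. A different share of αβ thymocytes and a trend with signal level had been set in advance as causes of a shift of the whole programme. With no such shift both stay open for it, although the thymocyte markers had a median of 0.59 (the sign set in advance as decisive means little beside a programme median near 0) and the programme's percentile after the loess correction was 55.9. A difference between the animals other than genotype, with 1 array each, is untested.

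Among the genes that differ most, a segment of another strain's chromosome left beside the disrupted gene could account for some. None of 62 genes above background among the 50 nearest on each side of H2-Ab1 was 2-fold apart (0 times the share of all genes). That was the outcome set in advance as going against it, but about 1.21 would be expected at that share and the upper 95% limit is 2.97 times, so these genes are too few to decide. Among the 9825 genes used for the scan of windows below, 117 were 2-fold apart, a lower share, at which fewer still would be expected. Farther off, 1 window of 20 consecutive genes held 5 that were 2-fold higher (H2-T10, Ppp1r11, Znrd1, Znrd1as and Gabbr1, the last 4 chosen after their values were seen), the most of any window on any chromosome against 4 elsewhere. Random placement of the 117 genes 2-fold apart in either direction among 9825 gave a highest count of 3 at the median. It put 5 at percentile 99.6. A strain segment is a candidate explanation for these 5, with shared regulation of neighbouring genes untested. The scan looks for clusters, so it cannot speak on strain differences at genes that lie singly or in smaller groups. A larger share of male cells would not account for Erdr1 at 4.39, since the highest of 3 Y-linked genes differed by 0.75, but it stays open for Mid1, which was at 1.79 as the mean of its 2 rows. The row of Erdr1 and the brightest row of Mid1 follow one another in the platform's numbering for the Y chromosome. Their differences may therefore not be separate, and a cause shared by both was not tested.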

How the results depend on the processing

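No paired analysis was possible because each group has 1 array, and for the same reason leaving out an array was not possible. Counting rows with identical values once, and percentiles other than with unmatched random lists, were chosen after the data were seen. The other scalings moved the median of all genes by at most 0.06 in size (-0.06, loess), and no list that stood apart and no named gene called 2-fold changed sign under any alternative run. Of 730 alternative values of named genes 8 moved by more than the spread of genes of like signal, and of 308 alternative list medians 48 moved by more than 1 SD of random lists. On 1 array alone 784 genes were above background and have only bounds. The causes of the moves below were not tested, except where fewer genes or another threshold make them.

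The count of higher genes went from 115 to 580 at 1.5-fold, 15 at 3-fold and 75 without predicted models and small RNAs. The count of lower genes went from 167 to 459 at 1.5-fold, 82 at 3-fold, 44 without predicted models and small RNAs, 105 with both arrays above background, 97 with the 75th percentile of all rows as background and 98 with identical rows counted once.

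The MHC class II median (-0.60) was -0.22 with values under background raised to it, -0.11 with no filter, -0.22 with both arrays above background, -0.34 with the median of all rows as background and -0.33 as a mean. Without members of other lists, the IL-17 programme (0.03) was at 0.093, the interferon gamma and cytotoxic programme (0.02) at -0.33 and the T cell receptor signal strength list (-0.09) at -0.0020. As means, the last 2 were -0.081 and -0.17, and the thymocyte markers (0.59) were 0.71. The loess correction gave -0.057 for the interferon gamma programme, 0.16 for proximal signalling (0.22) and 0.57 for mitosis (0.65). The median of all rows as background gave 0.14 for the interferon gamma programme, and the 75th percentile gave -0.14, and 0.74 for the thymocyte markers. Granulocyte markers (-0.33) were at -0.17 both with values raised to background and with no filter.

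Of 8 lists that stood apart, 3 lost that call under some alternative. The MHC class II list went to percentile 10.8 with no filter. The T cell receptor signal strength list went to 11.96 with no filter and 24.6 without members of other lists. The granulocyte list went to 3.93 after quantile normalization, 4.58 after the loess correction and 9.87 with values raised to background.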

Other observations

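The tests and gene families given here were chosen after the results they bear on had been seen. Histone genes were higher on the MHC class II KO array, with a median of 0.39 over 31 genes, 29 of them above 0 (percentile 100). The median was from 0.35 to 0.39 under the other scalings. The group was taken by gene name and not split by when in the cell cycle its genes are transcribed. The thymocyte markers, some from dividing cells, were higher there too (median 0.59, percentile 100). The Speer genes, a rodent family, were lower, with a median of -1.11 over 5 genes, all below 0 and 3 of them 2-fold or more (between -1.15 and -1.09 under the other scalings). The Gimap genes, GTPases of lymphocytes, had a median of 0.23 over 7 genes (percentile 91.4), with Gimap4 at 1.78 the highest. Small nucleolar RNAs had a median of 0.07 over 55.

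The V and J segments of the αβ receptor genes did not follow the double positive and αβ thymocyte markers. Over 85 segments above background the median was 0.03 (percentile 54.5), with 45 above 0 and 40 below, and it was -0.01 when centred on the median of all genes, while the marker list stood at 0.59.

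A hypothesis is that the MHC class II KO cells had received less recent stimulation through their receptor, which could lower Il17a and Il17f together with Ctla4 and the Nr4a genes. The signal strength list without Ctla4 had a median of -0.05 at percentile 6.48 of random lists, neither low enough to bear the hypothesis out nor near the middle. The immediate early and dissociation stress genes, which the test required low as well, were not, at a median of 0.06 and percentile 73.3. That list also holds stress genes, and 11 of its members were above 0 and 9 below (Hsph1 1.02, Fosl2 -1.11). Its median therefore cannot decide on receptor stimulation. Members of the signal strength list known to follow stimulation went both ways, Nr4a2 at -1.32 and Dusp2 at 1.19, so the hypothesis stays open.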
